A study of Mus musculus with 6 samples.

How the data were processed

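RNA from 6 samples of purified mouse spleen B cells was measured on 1-colour Illumina bead arrays, 3 samples labelled untreated and 3 labelled anti-IgM. Per the labels' protocols, total RNA was extracted with Trizol and cleaned on RNeasy columns, checked on a Bioanalyzer and amplified to biotinylated cRNA with an Ambion Illumina kit. The values used are the authors' processed value table, intensity per probe on a linear scale. The authors deposited these intensities already normalized between arrays. This was found from the values, in which the 1st percentile, the median, the 75th and the 99th percentile of the 6 arrays lay within 0.0702%, 0.0453%, 0.358% and 1.01% of each other. The normalization method, any aggregation of beads and the scanner software are not given in the sources used here. Background had not been subtracted in a way that reaches 0, since the lowest intensity was 34.4, so folds of dim genes are compressed. At the other end the highest log2 intensity of an array was between 15.52 and 15.74, and 50 genes tested had both group means within 1 of the lowest of these, where changes can be understated. A table of unnormalized signals was not used, because its 6 columns have names that match no sample label, and detection p-values were not analysed here.

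Samples were grouped by their titles. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these samples, part of which may be technical. No 2 arrays held identical values (0 pairs). The labels give both groups the replicate numbers 1 to 3. Whether the numbers pair the samples was checked on deviations from the group means over the probes tested. These correlated at 0.60, 0.27 and 0.32 for the pairs with numbers 1, 2 and 3. Each is over 0.1, so the numbers were taken to pair the samples, from the labels' numbers and this check. Deviations sum to 0 within a group, so a difference shared by replicate 1 alone makes the values among replicates 2 and 3 positive on balance. The check thus rests on pair 1. A fit with the replicate number as a block was run beside the main fit, which has group alone. Untreated replicate 2 with anti-IgM replicate 3 correlated at 0.39 and untreated replicate 3 with anti-IgM replicate 2 at 0.11, so the check does not tell pairs 2 and 3 from their exchange. No slide or scan date was analysed here.

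Intensities were taken as log2 with no further normalization. Without detection p-values, a probe was tested when it was above the array's median on at least 3 of the 6 arrays, the branch set for that case before the data were examined. This left 23505 of 45281 probes. Gene names came from the platform annotation, in which 34885 probes had 1 gene symbol, 18 had several and 10378 were not listed. Of the probes with 1 symbol, 34807 matched the RefSeq gene table (assembly GRCm38.p6) by Entrez ID and 78 did not, and no symbol needed an update (0). That table was used for names and for which genes lie on X or Y, and no coordinates are printed because the array's build is not given in the sources used here. Tested probes with 1 symbol numbered 19051, for 11855 genes. Each gene was represented by its probe with the highest mean log2 intensity, a choice that matters for the 4685 genes with 2 or more tested probes. Among 1972 genes with 2 or more significant probes, 33 had them in opposite directions, none of them a gene named by the rule below.

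Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend, design of group alone, two-sided), with Benjamini-Hochberg adjustment over the probes or genes tested and a threshold of 0.05. Each SE is from this fit and has 10.1 degrees of freedom at the median gene. For a gene with no probe above the array median on any array of 1 group, the change is a bound. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the array median and the probe's own value. Gene lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, adjusted over the 30 lists that had at least 5 members tested. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

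The 30 lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap. Gene models known only by an accession or a provisional name are skipped. It adds, for each list, the largest rise and the largest fall among called members, or the 2 largest where all went 1 way. Always named were Egr1, Myc, Cd69, Ccl3, Ccl4, Cd79a, Cd79b, Tcf3, Id3, Irf4, Prdm1 and Pax5. A gene of this rule, and 1 of 8 further lists written after the values were seen, are not reported here. This gave 78 genes, of which 77 were called. Any other gene is named because it belongs to a small count or was singled out after its values were seen.

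The analysis was tested on simulated data before use, with 200 of 11855 genes changed in a comparison made like anti-IgM against untreated. It called 18% of genes with a true log2 change of 0.5, 78% at 1, 98% at 2 and 100% at 3. Of 163 genes called, 16 were unchanged. Of 100 lists without an effect 0 were called, and a shifted list had an adjusted p of 2.19e-27 in camera. The simulated genes varied independently of each other and held no replicate 1 difference. This result therefore cannot show how often camera calls a list whose genes are correlated. Far fewer genes were changed than the 5581 called in the data, and the adjustment depends on that share. The percentages called therefore need not hold for the real comparison.

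The alternatives tried were quantile normalization again, normexp background correction with an offset of 50, median scaling and cyclic loess. Others were no filter on dim probes, a filter on all 6 arrays, limma without the trend, robust limma and array weights. The replicate block, an adjusted p under 0.01, limma's treat at a log2 change of 0.5, the mean over a gene's probes, an estimated correlation and each array left out in turn were also run. Leaving out both replicate 1 arrays, and genes on X and Y, were added after the data were seen. The planned background model from detection p-values was replaced, as set beforehand, by the branch for a table already normalized.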

Results

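Transcript levels were measured in B lymphocytes purified from the spleens of C57BL/6 mice, an inbred laboratory strain, at 8 weeks of age. There were 3 samples labelled untreated and 3 labelled as treated with anti-IgM. Goat antibody fragments against mouse IgM, which cross-link the B cell antigen receptor (BCR), were given at 2.5 µg/ml for 3 h. The protocols also name interleukin 4 (IL-4) at 5 ng/ml and the ligand of CD40 at 200 ng/ml, without saying which samples received them, so whether the untreated samples did is not known here. Each sample was read on 1 Illumina bead array with 45281 probes, and the median normalized intensity was 72.8 on every array. The number of arrays limits the precision, with a median standard error (SE) of 0.15 for the log2 change of a gene. All values below are log2 changes, anti-IgM minus untreated, ± SE from limma, with n = 3 in each group.

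The comparison asks which transcripts differed between splenic B cells given anti-IgM for 3 h and untreated ones. Were IL-4 and the ligand of CD40 given to the anti-IgM samples alone, their effects could not be told apart from those of anti-IgM. Chemokine genes and a G protein regulator were among the genes that rose most, and the quiescence factor gene Klf2 and the Myc antagonist gene Mxd4 were among those that fell most. Xcl1, a lymphocyte chemokine, rose 51.3-fold (5.68 ± 0.20; probe ILMN_2948552). Ccl3 and Ccl4, chemokines that attract T cells and macrophages, rose 33.4-fold (5.06 ± 0.15) and 17.3-fold (4.11 ± 0.12). The mean log2 intensity of Ccl4 was 15.29 in anti-IgM samples, close to the highest of the arrays, so its rise can be understated. Klf2, a transcription factor that keeps lymphocytes quiescent, was 24.9-fold lower (−4.64 ± 0.16; probe ILMN_2604029). The transcription factor gene Myc, a driver of cell growth, rose 8.25-fold, from a mean log2 intensity of 7.90 ± 0.06 (SD, n = 3) to 10.94 ± 0.18 (SD, n = 3).

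The gene with the highest rise was Rgcc, a regulator of the cell cycle that responds to complement, at 56.5-fold (5.82 ± 0.18; adjusted p = 1.51e-08, limma). Rgs16, which turns off G protein signals, rose by 4.58 ± 0.22, Chac1, which degrades glutathione, by 4.03 ± 0.18, and Fam83g by 3.63 ± 0.19. Fosl2, a member of the AP-1 transcription factor family, was not above the array median in any untreated sample, so its rise is a bound of at least 17.0-fold. The lowest measured change was that of B3gnt8, a glycosyltransferase gene, which was 27.8-fold lower (−4.80 ± 0.16; adjusted p = 1.61e-08, limma). Arhgef18 changed by −4.53 ± 0.17, and Marchf1, a ubiquitin ligase that removes MHC class II from the cell surface, by −4.50 ± 0.18. Rnase6 changed by −4.31 ± 0.13, Ralgps2 by −4.30 ± 0.12, Il16 by −4.23 ± 0.14 and Mxd4, an antagonist of Myc, by −4.15 ± 0.09. B3gnt8 and Marchf1 were above the array median in 2 of 3 anti-IgM samples and Chac1 in 2 of 3 untreated samples, so their changes can be understated and their rank among the others is not settled.

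At an adjusted p under 0.05 in limma, 5581 of 11855 genes tested differed, 2746 higher and 2835 lower with anti-IgM. Of these, 2359 changed at least 2-fold (1111 higher, 1248 lower) and 83 at least 8-fold (28 higher, 55 lower). Over all probes tested, 9919 of 23505 differed, 4991 higher and 4928 lower. The groups did not overlap in 6492 genes, 54.8% of those tested, where chance gives 10%. Of the 77 called genes named by the fixed rule, 16 of which were chosen for groups without overlap, they overlapped in Top2a, Lyz1 and S100a8. Each of these was lower with anti-IgM within every numbered pair. Among the 5581 called genes, 168 were not above the array median on any array of 1 group (66 of those that rose and 102 of those that fell), so their changes are bounds. The median log2 change of all genes tested was 0.02. The arrays had been normalized to nearly the same distribution. This median and the near balance of rises and falls therefore do not measure a change in total RNA per cell. With limma's treat at a log2 change of 0.5 in place of 0, 2777 genes passed.

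**Figure D1:**
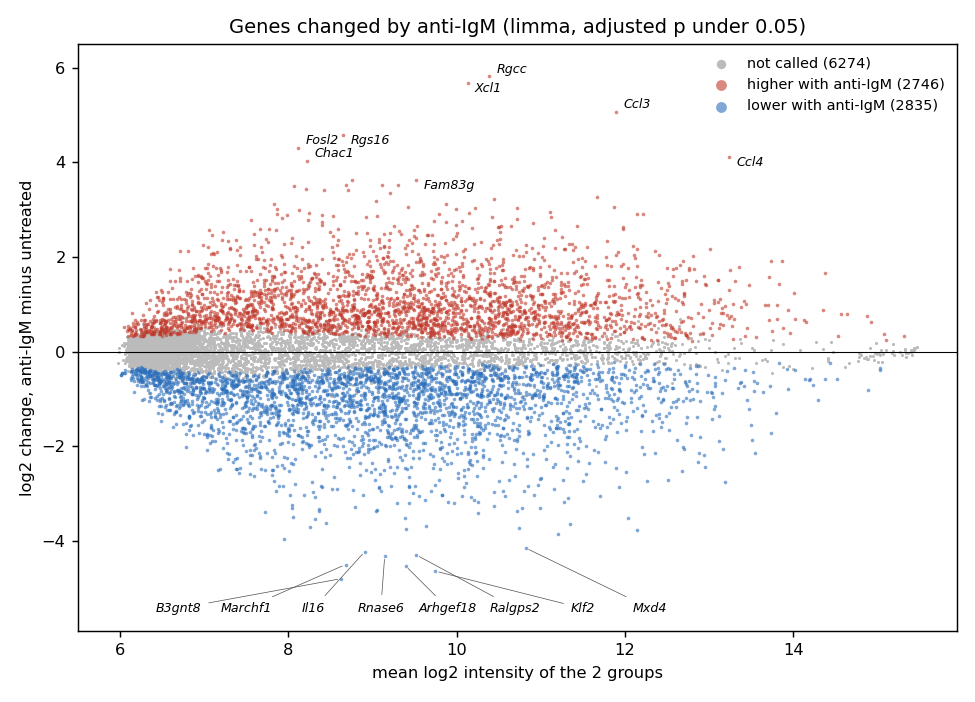
Log2 change (anti-IgM minus untreated, vertical axis) against the mean log2 intensity of both groups (horizontal axis), 1 point per gene, for 11855 genes. Red points mark the 2746 genes that rose and blue points the 2835 that fell (limma, adjusted p under 0.05). The 8 largest rises and 8 largest falls of the named-gene rule carry their names, with Rgcc at 5.82 and B3gnt8 at −4.80.

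**Figure D2:**
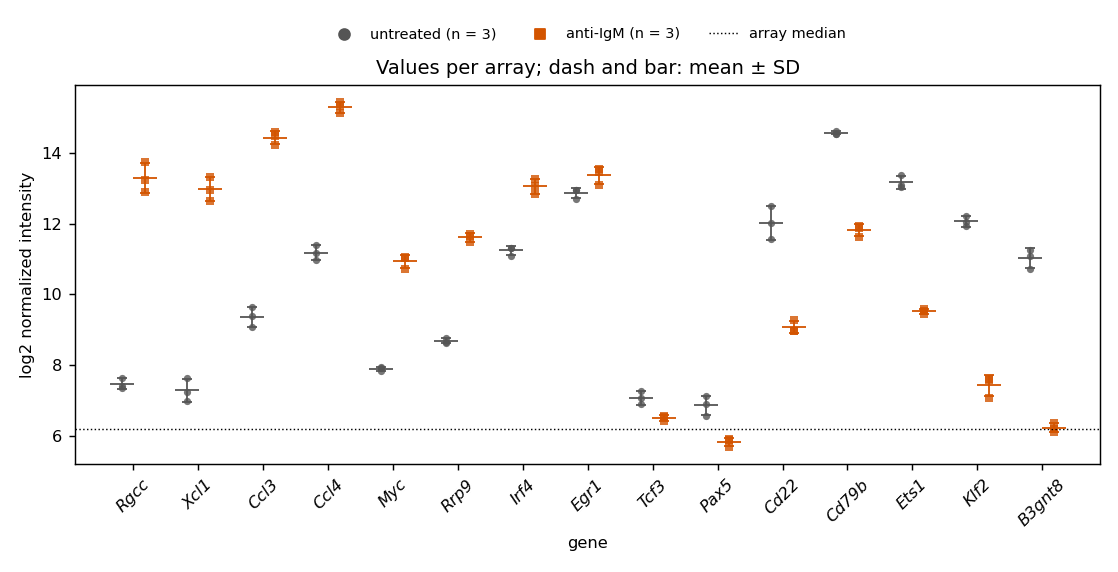
Log2 normalized intensity of 15 named genes in each array, with 3 untreated samples (grey circles) and 3 anti-IgM samples (orange squares); dashes and bars give the mean ± SD and the dotted line the array median. Myc has a mean of 7.90 in untreated and 10.94 in anti-IgM samples, while Cd79b goes from 14.57 to 11.81.

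The replicate 1 arrays of both groups stood apart from the other arrays. Pearson's r over the probes tested was between 0.981 and 0.992 within groups and between 0.898 and 0.912 across groups. The first principal component, with 81.2% of the variance, parted the groups. The next, with 11.0%, parted replicate 1 of both groups from replicates 2 and 3. Xist, the transcript that silences an X chromosome in female cells, had an intensity of 52.6 in replicate 1 of both groups. It had 1646 and 2031 in the other untreated samples, and 791 and 962 in the other anti-IgM samples. Eif2s3y, which lies on the Y chromosome in the GRCm38.p6 gene table, had 1043 and 516 in the replicate 1 samples and between 48.6 and 56.4 in the other samples. Over all 11855 genes tested, the log2 change had the same sign within the replicate 1 pair and in the mean of pairs 2 and 3 in 9522, and the changes correlated at r = 0.94 across genes, which are not independent replicates. Without both replicate 1 arrays 5697 of 10782 genes tested were called, a fit chosen after the arrays were seen. Of these, 5539 had the same direction in the replicate 1 pair, which that fit did not use.

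**Figure D3:**
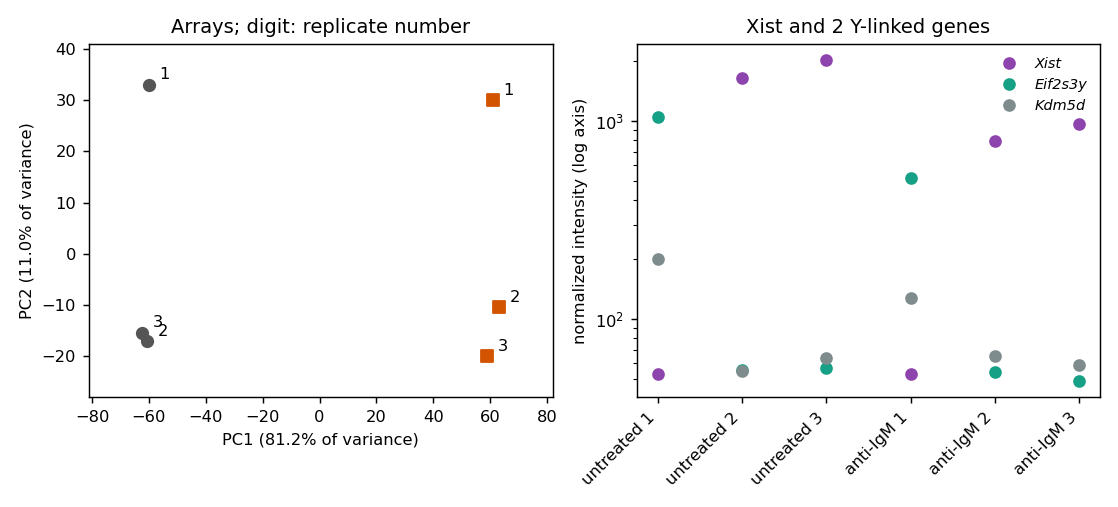
On the left, the 6 arrays on the first principal components (PC1, 81.2% of variance; PC2, 11.0%), with untreated samples as grey circles, anti-IgM samples as orange squares and the replicate number beside each. On the right, normalized intensity (log axis) of Xist and the Y-linked genes Eif2s3y and Kdm5d in each sample; replicate 1 of both groups has low Xist (52.6) and high Eif2s3y (1043 and 516).

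Immediate early transcription factors, the genes that antigen receptor signals switch on first, rose as a list. Of 16 measured members 11 rose and 1 fell, with a median change of 1.05 (camera adjusted p = 0.000142; adjusted p = 0.12 with an estimated correlation). Beside Fosl2 and Myc, Egr1 rose by 0.51 ± 0.13 (adjusted p = 0.0073) from a high untreated level of 12.87 ± 0.15 (SD, n = 3). The AP-1 subunit gene Jun changed the other way, by −1.07 ± 0.19. Of 19 NF-kB subunits, inhibitors and targets 12 rose and 2 fell, Bcl3 and Tnip1 (median 0.44; camera adjusted p = 0.013; adjusted p = 0.12 with an estimated correlation). Rel, the NF-kB subunit c-Rel, rose by 1.67 ± 0.13, and Bcl3, an atypical inhibitor of the family, changed by −0.93 ± 0.17.

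Among cytokines and chemokines, 9 of 15 members rose and 4 fell, with a median of 1.38 (camera adjusted p = 0.021; adjusted p = 0.28 with an estimated correlation). The list missed the threshold when only probes above the median of all 6 arrays were tested (adjusted p = 0.12). The members that fell were Ltb, Il12a, Ebi3 and Ccl5, and Ltb, which encodes lymphotoxin beta, changed most (−3.05 ± 0.17). In the same samples Nkg7, a marker of natural killer cells, rose by 1.20 ± 0.21, and Klrd1, another, changed by −0.78 ± 0.15. Of 18 feedback inhibitors of MAP kinase, G protein and cytokine signalling, 8 rose and 3 fell (median 0.34). This list did not pass the test without the pairing (camera adjusted p = 0.079) and did with the replicate block (adjusted p = 0.033) or without both replicate 1 arrays (adjusted p = 0.030). With an estimated correlation it passed neither without the block (adjusted p = 0.23) nor with it (adjusted p = 0.24). Rgs16 was its largest rise, and Dusp6, a phosphatase that inactivates ERK, its largest fall (−1.61 ± 0.15). Activation markers at the cell surface went both ways, with 7 of 15 higher and 5 lower (median 0.29; camera adjusted p = 0.25). Tfrc, the transferrin receptor, rose by 2.64 ± 0.17 and the early marker Cd69 by 0.98 ± 0.12, while Cd40, the costimulatory receptor, changed by −1.51 ± 0.12.

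Genes of ribosome assembly rose together. Of 22 measured members of the list ribosome biogenesis and nucleolus, 21 rose and none fell, 20 of them at least 2-fold. The median change was 1.94 (camera adjusted p = 1.06e-12). This was the only list of the 30 that kept its call with an estimated correlation (adjusted p = 0.034), and with the replicate block as well it did not (adjusted p = 0.23). Rrp9, a component of the small-subunit processome, rose by 2.93 ± 0.11 and Polr1b, a subunit of RNA polymerase I, by 2.47 ± 0.12. Dkc1 was the member that did not pass (0.17).

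Genes that supply and charge amino acids rose too. In the list of amino acid transport, serine and one-carbon metabolism, 11 of 14 members rose and 1 fell (median 1.27; camera adjusted p = 0.000155; adjusted p = 0.12 with an estimated correlation). Asns, asparagine synthetase, rose 10.6-fold (3.41 ± 0.15), and the glutamine transporter gene Slc38a2 changed by −0.60 ± 0.15. Of 17 aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 14 rose and 2 fell, Vars and Qars (median 1.22; camera adjusted p = 5.53e-05; adjusted p = 0.12 with an estimated correlation). Iars, for isoleucine, rose by 1.71 ± 0.11 and Vars, for valine, changed by −0.96 ± 0.14. For glycolysis and glucose or lactate transport, 8 of 13 rose and 1 fell (median 0.40; camera adjusted p = 0.0085; adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, 9 rose. Pgam1, a glycolytic mutase, rose by 1.78 ± 0.12 and Hk1, a hexokinase, changed by −0.65 ± 0.16. Of 15 heat shock and cell stress genes 10 rose and 2 fell, Ddit4 and Gadd45a (median 0.91; camera adjusted p = 0.0025; adjusted p = 0.12 with an estimated correlation). Trib3, a target of the integrated stress response, rose by 3.13 ± 0.21, and Ddit4, an inhibitor of mTORC1, changed by −2.37 ± 0.14.

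Genes of the antigen receptor's own machinery fell as a list. Of 20 BCR components and proximal signalling genes 14 fell and 4 rose (15 and 4 adjusted over the list alone), with a median of −0.98, or −0.90 with Syk at its bound (camera adjusted p = 0.000158; adjusted p = 0.12 with an estimated correlation). Cd79b, a signalling chain of the receptor, was 6.78-fold lower (−2.76 ± 0.10), from the high untreated level of 14.57 ± 0.05 (SD, n = 3). That level is within 1 log2 unit of the lowest array maximum of 15.52, so the fall can be understated. The members that rose were Fyn, Pik3ap1, Bcl10 and Malt1, and the Src family kinase gene Fyn rose most (2.27 ± 0.18). Cd79a, which encodes the partner chain, was not analysed here. Inhibitory receptors and phosphatases of the BCR fell alongside, with 12 of 16 lower and none higher (median −1.21; camera adjusted p = 7.44e-05; adjusted p = 0.090 with an estimated correlation). Sla, an adaptor that promotes receptor degradation, changed by −3.18 ± 0.14, and Cd22, an inhibitory lectin of B cells, by −2.95 ± 0.20.

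Transcription factors of B cell identity fell as well. Of 19 members of that list, which includes the E proteins, 15 fell and 1 rose (median −0.99, or −0.78 with Pax5 at its bound; camera adjusted p = 0.000197; adjusted p = 0.23 with an estimated correlation). Ets1 was 12.5-fold lower (−3.65 ± 0.11). Tcf3, which encodes the E2A proteins, changed by −0.57 ± 0.15 (adjusted p = 0.0091, limma). Its mean log2 intensity was 7.08 in untreated and 6.51 in anti-IgM samples, dim values at which folds are compressed. Id3, an inhibitor of E proteins, changed by −1.03 ± 0.23 (adjusted p = 0.0030, limma). Id2, another such inhibitor, was the member that rose (1.01 ± 0.16). Pax5 was dim in untreated samples too (mean log2 intensity 6.87). It was not above the array median in any anti-IgM sample, so it was at least 1.60-fold lower.

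Genes of quiescence and lymphocyte trafficking gave the lowest camera p among the lists that fell. Of 18 members 12 fell and 1 rose (median −1.24; camera adjusted p = 5.53e-05; adjusted p = 0.090 with an estimated correlation), with Klf2 the largest fall. Gpr183, an oxysterol receptor that guides B cells, was the member that rose (0.26 ± 0.09; adjusted p = 0.040). It missed the threshold without untreated replicate 2 (0.056) or 3 (0.15) and without anti-IgM replicate 1 (0.075), 2 (0.071) or 3 (0.10). Of 9 marginal zone markers, genes typical of a B cell subset of the spleen, 5 fell and 1 rose (median −1.30; camera adjusted p = 0.013; adjusted p = 0.12 with an estimated correlation). Pld4 changed by −2.83 ± 0.12 and the tetraspanin gene Cd9 rose by 1.90 ± 0.22. The others that fell were Mzb1, Cd1d1, Asb2 and Dtx1.

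Genes of MHC class II antigen presentation fell as a list. Of 12 members 8 fell and none rose (median −1.06; camera adjusted p = 0.0035; adjusted p = 0.27 with an estimated correlation). Ciita, the master activator of these genes, was 7.15-fold lower (−2.84 ± 0.31) and H2-DMa, a subunit of the peptide editor, 3.69-fold lower (−1.88 ± 0.16). The members not called were H2-Aa (−0.17), H2-Ab1 (0.05), H2-Eb1 (0.17) and Cd74 (0.02). The last 3 read above log2 15 in both groups, close to the highest intensity of the arrays, so a change in them can be understated. Cst3 and Adgre1, markers of dendritic cells and macrophages, which also present antigen, were lower in the same samples (−1.22 ± 0.20 and −2.10 ± 0.22), Adgre1 being above the array median in 2 of 3 anti-IgM samples. The dendritic cell markers Zbtb46 and Bst2 rose (1.76 ± 0.14 and 0.56 ± 0.15), and 8 of 10 macrophage markers did not pass the test. Type I interferon responsive genes fell, with 9 of 13 lower and 1 higher, or 10 and 1 adjusted over the list alone. Their median was −0.99, or −0.72 with Irf7 and Mx2 at their bounds (camera adjusted p = 0.0013; adjusted p = 0.23 with an estimated correlation). The list missed the threshold when only probes above the median of all 6 arrays were tested (adjusted p = 0.081). Stat2, a signal transducer of interferon receptors, changed by −2.20 ± 0.26, and was above the array median in 2 of 3 anti-IgM samples. Isg15 rose by 0.51 ± 0.17 (adjusted p = 0.032), and missed the threshold without untreated replicate 1 (0.090) or 2 (0.075) and without anti-IgM replicate 2 (0.063) or 3 (0.13). Of 18 calcium, calcineurin and NFAT genes 10 fell and 4 rose, Orai1, Rcan1, Camk4 and Stim2 (median −0.54; camera adjusted p = 0.018; adjusted p = 0.34 with an estimated correlation). Ppp3ca, the catalytic subunit of calcineurin, changed by −2.43 ± 0.13, and Orai1, the pore of the store-operated calcium channel, rose by 2.16 ± 0.13.

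**Figure D4:**
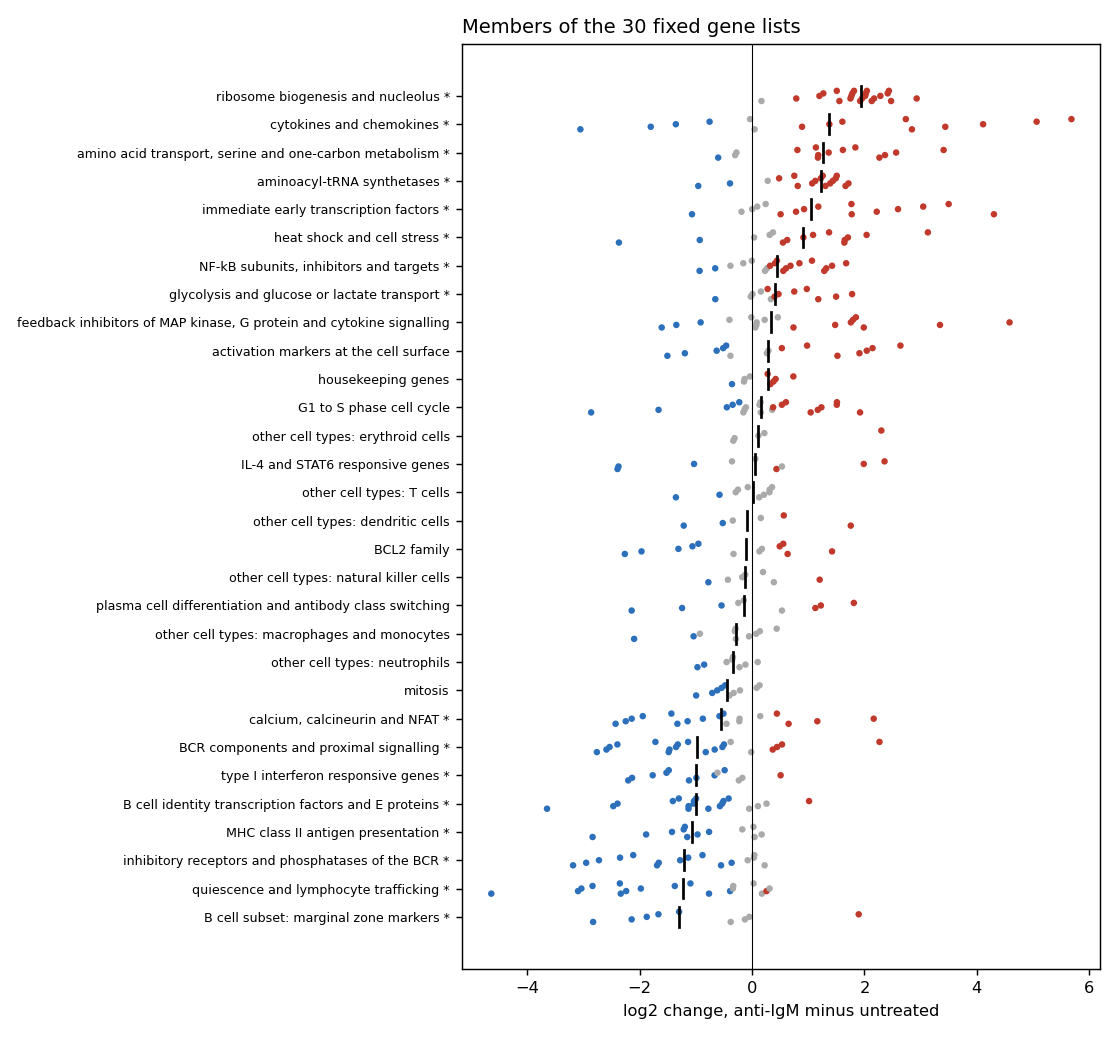
Log2 change (anti-IgM minus untreated, horizontal axis) of every measured member of the 30 gene lists, 1 row per list, sorted by the list's median (black bar). Red points rose and blue points fell (limma, adjusted p under 0.05), grey points were not called, and a star marks the 16 lists that differed from other genes (camera, preset correlation), from ribosome biogenesis (median 1.94) to marginal zone markers (−1.30).

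The remaining lists of B cell programmes held large changes in both directions and did not pass the test against other genes. For plasma cell differentiation and antibody class switching 3 of 9 rose (Irf4, Ung and Batf) and 3 fell (Mzb1, Sdc1 and Creb3l2), or 3 and 4 adjusted over the list alone (median −0.15, mean 0.04; camera adjusted p = 0.91). Irf4, a transcription factor of activated B cells and plasma cells, rose by 1.81 ± 0.12, and Mzb1, a chaperone of secreted antibody, changed by −2.14 ± 0.09. Prdm1, which encodes the plasma cell regulator Blimp-1, did not pass the test (−0.15 ± 0.13; adjusted p = 0.42) and was above the array median in 2 of 3 samples of each group. For IL-4 and STAT6 responsive genes 3 of 9 rose and 3 fell (median 0.06, mean −0.09; camera adjusted p = 0.91). Gfi1 rose by 2.36 ± 0.14 with Cish and Stat6, and Bcl6, a repressor of plasma cell fate, changed by −2.39 ± 0.23 with Fcer2a and Il4ra.

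Neither cell cycle list passed the test against other genes. Of 21 genes of the G1 to S phase 9 rose and 5 fell, or 10 and 5 adjusted over the list alone (median 0.16; camera adjusted p = 0.27). Ccnd2, the D cyclin of B cell activation, rose by 1.92 ± 0.18, and E2f2 changed by −2.86 ± 0.17. Of 10 mitosis genes 5 fell and none rose (median −0.44; camera adjusted p = 0.056, and 0.033 without untreated replicate 3; adjusted p = 0.27 with an estimated correlation). The mitotic kinase gene Aurkb changed by −0.99 ± 0.13 and the topoisomerase gene Top2a by −0.71 ± 0.23 (adjusted p = 0.025). Top2a missed the threshold without untreated replicate 1 (0.061) or 2 (0.065) and without anti-IgM replicate 2 (0.10) or 3 (0.066). In the BCL2 family of apoptosis regulators 4 of 12 rose and 5 fell, or 4 and 6 adjusted over the list alone (median −0.10; camera adjusted p = 0.37). The survival gene Bcl2l1 rose by 1.42 ± 0.15, and the death-promoting gene Bmf changed by −2.26 ± 0.16. Of 9 housekeeping genes 5 rose and 1 fell (median 0.28; camera adjusted p = 0.38). Hprt rose by 0.73 ± 0.12 and Rpl13a changed by −0.36 ± 0.12 (adjusted p = 0.035), in the same directions under every scaling tried. Each scaling started from intensities already normalized between arrays, so the shared directions are no independent check. Rpl13a missed the threshold without untreated replicate 1 (0.11) or 2 (0.073) and without anti-IgM replicate 3 (0.13).

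No list of markers for other cell types that a spleen preparation can hold passed the test. For T cells 2 of 10 markers fell and none rose (median 0.02, mean −0.12; camera adjusted p = 0.53), with Cd28 at −1.35 ± 0.16 and Cd8b1 at −0.58 ± 0.10. For natural killer cells 1 of 7 rose and 1 fell (median −0.12, mean 0.04; camera adjusted p = 0.91), with Nkg7 as the rise and Klrd1, above the array median in 1 of 3 anti-IgM samples, as the fall. For macrophages and monocytes 2 of 10 fell (median −0.29; camera adjusted p = 0.32), Adgre1 and the lysozyme gene Lyz1 (−1.04 ± 0.31; adjusted p = 0.017). Lyz1 missed the threshold without untreated replicate 2 (0.070) or 3 (0.084) and without anti-IgM replicate 2 (0.062). For neutrophils 2 of 8 fell, or 1 adjusted over the list alone (median −0.35; camera adjusted p = 0.27), S100a9 (−0.85 ± 0.22) and S100a8 (−0.97 ± 0.32; adjusted p = 0.030). S100a8 missed it without untreated replicate 2 (0.12) or 3 (0.14) and without anti-IgM replicate 1 (0.064) or 2 (0.096). These fits ignore the pairing. On all 6 arrays with the replicate block, limma gave adjusted p = 4.1e-08 for Lyz1 and 7.4e-06 for S100a8. For dendritic cells 2 of 6 rose and 2 fell (median −0.09, or −0.03 with Xcr1 at its bound, mean 0.07; camera adjusted p = 0.91), with Zbtb46 at 1.76 ± 0.14 and Bst2 higher, and Cst3 and Xcr1 lower. For erythroid cells 1 of 5 rose (median 0.11; camera adjusted p = 0.62), Car2, a carbonic anhydrase (2.30 ± 0.19).

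In all, camera called 16 of the 30 lists, 8 higher and 8 lower than other genes. Of the 17 lists called without both replicate 1 arrays, each had a median on the same side in the replicate 1 pair. Over all 30 lists the median had the same sign within the replicate 1 pair and in pairs 2 and 3 in 23. The other 7, none of them called, were IL-4 and STAT6 responsive genes and the markers of T cells, macrophages, neutrophils, dendritic cells, natural killer cells and erythroid cells. Among these, macrophage and neutrophil markers differed most, with medians of 0.058 and 0.001 in the replicate 1 pair and −0.44 and −0.54 in pairs 2 and 3. In untreated samples their median log2 difference, replicate 1 minus the mean of replicates 2 and 3, was −0.32 and −0.67. With an estimated correlation 1 list passed. By fry, which does not compare a list with other genes, 25 lists moved on balance one way and 29 changed in either direction. Where no count adjusted over the list alone is given for one of the 30 lists, it equalled the count over all genes tested, and 12 genes stood in more than 1 list.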

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

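Both fits that leave out the replicate 1 arrays together or genes on chromosomes X and Y were chosen after the data were seen, and all others before the data were examined. No named gene turned direction in the 18 settings run for them, and no called list in its 18. Of the lists not called, 3 turned in at least 1 setting, IL-4 and STAT6 responsive genes and the markers of natural killer and dendritic cells, each without a call. Lists and named genes were not run with an adjusted p under 0.01, treat or the mean over probes. Which direction held more calls also turned, for probes with cyclic loess (4684 higher, 5191 lower), the replicate block (5836 and 5949) or any 1 anti-IgM array left out, and for genes with the mean over probes (2812 and 2765) or without untreated replicate 1 (2746 and 2670). With limma's treat at a log2 change of 0.5, 4458 probes and 2777 genes passed in place of 9919 and 5581. With an estimated correlation 1 list passed in place of 16. With 1 array left out in turn, counts were 8276 to 9447 probes, 4901 to 5416 genes, 2295 to 2375 genes with at least 2-fold change, and 16 to 17 lists. All other counts stayed within 1.5 times, and the share of called genes that rose was between 46.5% and 50.7%. Every setting used intensities already normalized between arrays, so this near balance is no independent result. With the replicate block limma called 11785 probes, 6397 genes (5579 of the 5581 among them), 2361 with at least 2-fold change, and 17 lists. Beyond the feedback inhibitors, and ribosome biogenesis with an estimated correlation, the block changed no other call of the 30 lists or of a named gene. Without both replicate 1 arrays there were 10093 probes, 5697 genes, 2334 with at least 2-fold change, and 17 lists. Without X and Y there were 9704 probes, 5430 genes, 2302 with at least 2-fold change, and 16 lists.

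Of the 78 named genes 72 kept their direction and their side of the threshold in every setting that tested them. Not every setting tested Fosl2 and Pax5 (13 of 18 each), Klrd1 (16) and Chac1, Hprt, Marchf1, Prdm1 and Stat2 (17 each). The other 6 were Gpr183, Isg15, Rpl13a, Top2a, Lyz1 and S100a8. In limma with the replicate block their adjusted p was 0.018, 0.00061, 0.0018, 2.4e-05, 4.1e-08 and 7.4e-06, in this order. The fits with 1 array left out did not use the block. Beyond the arrays named in the results, Gpr183 (adjusted p = 0.057) and Isg15 (0.055) missed the threshold in limma with cyclic loess, Gpr183 with no filter (0.065) or no trend (0.098), Rpl13a with no trend (0.072), and Lyz1 (0.10) and S100a8 (0.091) in robust limma. The feedback inhibitors also passed with no filter (0.030). Mitosis passed with cyclic loess (0.042), with no filter (0.039) and without untreated replicate 3 (0.033). Cytokines and chemokines (0.12) and interferon responsive genes (0.081) were lost with probes above the median on all 6 arrays, a setting that tests fewer genes. The other causes were not tested. No normalization and the value table itself coincided with the values reported. A chip block was not run because no chip is analysed here. Signal over background limits dim genes, since 168 of the called genes were not above the array median on any array of 1 group.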

Other observations

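The gene lists described first were written after the values had been seen, and so were the tests of a shared day and of T and natural killer cells. The test of sex itself and the splits of the samples were set out before their results were seen. Adjusted p-values of these lists are over the 8 lists written then; as the lists were chosen with the values known, they describe these samples and are no independent test. All 12 measured translation initiation factors rose (median 1.45; limma's camera adjusted p = 1.4e-07; adjusted p = 0.017 with an estimated correlation), led by Eif2b3 (2.62 ± 0.10, SE, n = 3 per group). Of 17 genes of mitochondrial protein import and chaperones 16 rose (median 1.23; adjusted p = 0.017 with an estimated correlation), led by Timm10 (2.44 ± 0.10) and Tomm40 (2.37 ± 0.14). Of 21 purine and pyrimidine synthesis genes 15 rose and 3 fell, Rrm2, Prps2 and Ctps2, or 15 and 4 adjusted over the list alone (median 1.17; adjusted p = 0.021 with an estimated correlation), and Ctps, which makes CTP, rose by 2.64 ± 0.10. With an estimated correlation and the replicate block none of these 3 lists passed (adjusted p = 0.071, 0.071 and 0.087). Of 13 cholesterol synthesis genes 10 rose (median 0.99; camera adjusted p = 7.57e-05; adjusted p = 0.16 with an estimated correlation), with Cyp51 at 2.18 ± 0.11. Of 39 genes for proteins of the cytosolic ribosome 1 rose and 3 fell, or none and 1 adjusted over the list alone (median −0.07; camera adjusted p = 0.14). In 27 of the 39, both group means were within 1 log2 unit of the lowest array maximum of 15.52, so changes in them can be understated, and the list was not compared with ribosome assembly.

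Of 15 lysosome genes 10 fell and 1, Ctsz, rose, or 10 and 2 adjusted over the list alone (median −0.73; camera adjusted p = 0.0011; adjusted p = 0.037 with an estimated correlation, and 0.094 with the replicate block as well), and the protease gene Lgmn was 7.01-fold lower (−2.81 ± 0.12). Among 13 circadian clock genes 7 rose and 2 fell, Arntl and Dbp (median 0.39; camera adjusted p = 0.020; adjusted p = 0.37 with an estimated correlation). Ciart, a repressor of the clock, rose 12.3-fold (3.62 ± 0.16), with its 3 probes between 3.62 and 3.81. Per2 rose by 1.96 ± 0.15, though its probes ranged from 0.31 to 1.96, and Dbp changed by −0.99 ± 0.16.

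For 55 genes, levels were at least 8-fold lower after 3 h of anti-IgM than in the untreated samples. These are separate samples, and the arithmetic here assumes that they stand for the start of the 3 h. If transcription had stopped at once and completely, and if normalized intensity followed the amount of RNA per cell, a fall of 8-fold in that time corresponds to a half-life of 60 min. By the same arithmetic the fitted changes correspond to 37.5 min for B3gnt8, 38.8 min for Klf2 and 43.4 min for Mxd4, with no allowance for their SE. A rise in total RNA per cell would make the true times longer. Background left in the intensities would make them shorter, most of all for B3gnt8, which was above the array median in 2 of 3 anti-IgM samples. None of these assumptions was tested, and decay was not measured here.

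The replicate 1 arrays of both groups stood apart from the others in Xist, in Y-linked genes and in many autosomal genes. Mice of another sex as the source of the replicate 1 samples is consistent with Xist, at −5.12 in untreated and −4.05 in anti-IgM samples against the other arrays on the log2 scale, and with the Y-linked genes, whose median difference was at least 1.04; Uty moved by 0.60 and 0.27, short of the predicted 1. With no filter on dim probes, 62 genes were off by over 1 in the same direction in both groups, 6 of them on X and 2 on Y, with Cish (2.18 and 1.82) and Ddx5 (−1.83 and −1.57) among the autosomal ones. Whether sex accounts for these too is open, since sex can also change autosomal genes. A shared day, batch or array position cannot be told apart from a difference between mice, because both fall on the same arrays; autosomal deviations of the replicate 1 arrays correlated at 0.562 between the groups.

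Xcl1, Il2 (1.61 ± 0.15; above the array median in 1 of 3 untreated samples), Ifng (2.21 ± 0.16), Tbx21 (2.89 ± 0.27) and Nkg7, genes best known from T and natural killer cells, rose with anti-IgM in purified B cells. A larger share of such cells in the anti-IgM samples stays open. The 16 other T and natural killer cell markers had a median change of −0.098 (95% bootstrap interval −0.34 to 0.21, from resampling markers and not samples). Their changes had both signs, and those called, Cd28, Cd8b1 and Klrd1, were all lower. Only 5 had an untreated mean over 1 log2 unit above the array median, so the median cannot settle this. T or natural killer cells present in both groups that answered the treatment may also be the source, and this stays open, since 1 of 4 measured T cell receptor subunit genes, Cd3d, was above the array median on all 6 arrays. Its mean log2 intensity was 6.78 in untreated and 6.99 in anti-IgM samples. B cells themselves as the source, a biological explanation, was not tested.

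The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In limma the real split gave 9919 probes, 5581 genes and 2359 genes with at least 2-fold change, and the highest of the other splits gave 0 of each. It gave 16 lists, where the highest of the others gave 11. For each of these results 1 split, the real one, gave a value as large. The splits that also part all 3 numbered pairs gave 11, 6 and 9 lists. In every split but the real one, each group mixes untreated and anti-IgM samples. The treatment difference then counts as spread within the groups. The counts of 0 probes and genes are therefore no measure of what arises without an effect. Nor are the counts of lists, since the mixing is uneven and part of the treatment difference stays between the groups. The other 6 splits keep 2 numbered pairs whole.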
